A study of Mus musculus with 6 samples.

How the data were processed

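Bulk RNA sequencing was done on 6 subcutaneous CT26 tumors, a colorectal carcinoma line grown in mice of its own BALB/c strain, of which 3 came from vehicle-treated animals and 3 from animals given TP-18. Per the labels, total RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 RNA-seq kit, and the submitters name fastp, HISAT2, HTSeq and the mouse build GRCm38. Versions of these tools, the strandedness of the libraries and the handling of reads that map to several places are not given in the sources used here. The deposited count table holds whole-number counts per gene for each tumor, with no normalization. The deposited FPKM table was made by the authors by dividing each count by a whole-number gene length and by the total count of its library, which was checked in 15884 genes. Both tables cover 23122 genes with a symbol and an Entrez ID, of which 17574 are protein-coding, and none was 0 in every library. Entrez IDs were looked up in the RefSeq annotation of GRCm38.p6 for coordinates, and 22465 matched.

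Groups were taken from the labels as 3 vehicle and 3 TP-18 tumors. The labels do not say that each sample came from a separate mouse, so each p-value covers at most the spread between these samples. Total counts ran from 34813482 to 36489081 per library. Levels are given as CPM, counts scaled to library size. Errors cover the spread between libraries, while the bootstrap interval of matched genes covers only the spread between genes. Neither says anything of PCR copies, which cannot be recognized in count tables.

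Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group as design (minimum count 10, minimum total 15), which left 14189. Libraries were scaled by TMM, the model held the group alone, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 in the robust quasi-likelihood F test, which is two-sided. Log2 fold changes are TP-18 minus vehicle, with edgeR's prior count of 0.125, and their standard errors (SE) were derived from the F statistic. CPM values are TMM-scaled and are given as mean ± SD over the 3 tumors of a group.

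Gene lists were written before the data were examined, as were the tests of genes and of lists, the rule for named genes and all alternatives other than the one named below. The ribosomal and immediate early gene comparisons, the pathway terms and the tests of host tissue and of scaling were chosen after the results had been seen. There were 32 lists (15 of pathways, 11 of cell types, 4 of other tissues and 2 of RNA quality) with 511 symbols, of which 473 matched a gene by symbol, 20 by a synonym and 18 not at all. The 18 include Trac, Trbc2, Ighm and Igkc, which are not analysed here. Lists overlap little, with 5 genes held by 2 lists, but T cell, cytotoxic and NK cell lists hold genes that several lymphocyte types express. Each list was compared with all other tested genes by camera in limma 3.58.1 with a preset correlation of 0.01, and adjusted over the 32 lists. Beside each such p that passed with all 6 libraries stands the one obtained with the correlation estimated from the data, while p-values that missed the threshold or come from fewer libraries are given for the preset correlation alone, and beside each count of members stands the count adjusted over the list alone. A list score is the mean log2 CPM of its tested members in a library.

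Named genes are of 3 kinds: the 10 largest increases and the 10 largest decreases among protein-coding genes past the threshold with a mean log2 CPM of at least 0 and no overlap between groups, up to 4 members of each called list and up to 2 of each other list by smallest p, and 16 genes fixed in advance for the receptors targeted and for tumor immunity. Any gene outside that rule is said to have been chosen after its values were seen.

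The alternatives were RLE and upper-quartile scaling, no filter on low counts, a filter of 1 CPM in 3 libraries, non-robust moderation, the replicate number as a block, leaving out each library in turn, DESeq2 1.42.0, limma-voom, limma on log2 FPKM with pseudocounts of 1 and 0.1 and without a filter on low FPKM (limma's trend test), an adjusted p under 0.10, and a further minimum of a 2-fold change. For lists, fry, an estimated correlation and camera on FPKM were also run. Leaving out vehicle 3 and TP-18 3 together was added after seeing the data. The labels state no pairing of tumors by replicate number, so no paired value is used in the comparisons. Deviations of tumors with equal numbers from their group means correlated at 0.24, -0.08 and -0.04 across genes. Only TP-18 1 correlated most with the vehicle tumor of its own number. With so few tumors these values cannot exclude a weak pairing.

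The procedure was tested on simulated data with the same layout, in which genes were drawn independently of each other. Of genes changed 2-fold 77 of 100 were recovered and of genes changed 4-fold 89 of 100, with 17 false calls. Beside 77 and 89 true calls, these 17 are a larger share of calls than the adjusted p threshold of 0.05 aims at. The simulation therefore does not show that the threshold was held for genes. How much this share varies between draws was not tested. In a separate draw 3 of 3 raised lists and 0 of 29 others were called. In the tumors genes of a list can move together, with an estimated correlation of 0.75 for interferon gamma response genes. The simulation therefore does not show how often lists are falsely called here. Pathway terms came from KEGG and Reactome, as the deposited count table annotates its genes. Those with 10 to 300 genes in the background of tested, annotated genes were tested for an excess of called genes. The test was one-sided and hypergeometric and was chosen after the results had been seen. It treats genes as independent and holds no spread between tumors, so its p-values do not cover genes that move together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. A test for lymph node tissue in the samples is not reported here. No sample was left out, and nothing was removed from the count table before filtering.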

Results

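The series holds RNA sequencing of 6 tumors from female BALB/c mice aged 6 to 8 weeks. Each tumor grew from 500000 CT26 cells, a murine colorectal carcinoma line, injected under the skin, and animals were assigned at random to 2 groups once tumors measured 100 to 200 mm3. One group received vehicle and the other TP-18, which the series title describes as an antagonist of both EP2 and EP4, receptors for prostaglandin E2, at 50 mg/kg by mouth once daily for 3 weeks. There were 3 tumors per group. The vehicle libraries held 35163739, 34813482 and 34882701 counts, with 18429, 18592 and 18769 genes detected. The TP-18 libraries held 35470258, 35347034 and 36489081 counts, with 19278, 19464 and 19617 genes detected. Eef1a1, a translation elongation factor, was the most abundant gene in every library and took 1.42% to 2.07% of the counts.

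Pearson correlations of log2 CPM across the 14189 tested genes were 0.983 to 0.988 between TP-18 tumors, 0.968 to 0.985 between vehicle tumors and 0.958 to 0.975 across groups, and genes are not independent replicates. The first principal component took 51.1% of the variance and put the vehicle tumors at -27.1, -43.1 and -42.0 and the TP-18 tumors at 31.1, 41.5 and 39.6. The second took 25% and ran mainly between vehicle 1 at 38.9 and vehicle 3 at -44.5, which also differed in blood and inflammatory cell genes as given further on.

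The comparison of TP-18 with vehicle asks which transcripts of a CT26 tumor differ after 3 weeks of treatment. Ifng, which encodes interferon gamma, and the interferon-induced chemokines Cxcl9 and Cxcl10 were higher in every TP-18 tumor than in any vehicle tumor. Ifng (Entrez 15978, chromosome 10, 118441046 to 118445894 in GRCm38) went from 0.318 ± 0.174 to 3.46 ± 1.16 CPM (SD, n = 3 per group), a log2 change of 3.42 ± 0.50 (SE) with an adjusted p of 0.00727, on 32 reads in vehicle and 387 in TP-18 tumors. Cxcl9 (Entrez 17329, chromosome 5, 92321331 to 92328079), a chemokine that draws activated T cells, went from 25 ± 8.85 to 204 ± 38.2 CPM, 8.14-fold, and its neighbour Cxcl10 (Entrez 15945, chromosome 5, 92346638 to 92348889) from 15.3 ± 0.98 to 61.7 ± 9.23 CPM, 4.03-fold. Their adjusted p-values were 0.00412 and 0.00082. By camera with a preset correlation, lists of T cell, NK cell, dendritic cell, antigen presentation and skeletal muscle genes were higher alongside and red blood cell markers lower, but no list passed with an estimated correlation. The globin calls were lost without vehicle 2 or any one TP-18 library.

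**Figure D1:**
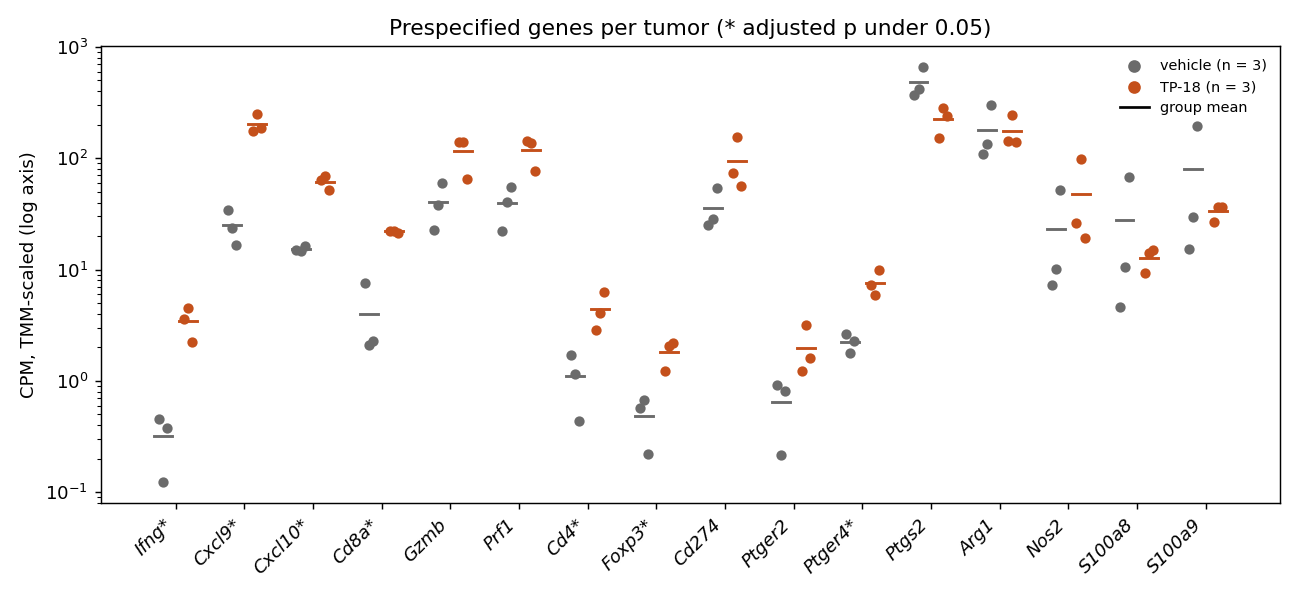
CPM on a log axis of the 16 genes fixed in advance, with a point per tumor and a line at each group mean for vehicle (grey, n = 3) and TP-18 (orange, n = 3). Stars mark adjusted p under 0.05: Cxcl9 rose from a mean of 25 to 204 CPM, while the group means of Arg1 were 181 and 175 CPM.

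By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1006 genes were higher and 747 lower in TP-18 tumors, 12.4% of those tested, and 980 and 721 of these were protein-coding. Higher calls were larger in size: 636 were higher by at least 2-fold and 57 lower by that much. All 1753 calls showed no overlap between groups, as did 35.8% of all tested genes, where chance gives 10% for 3 against 3. The number of calls changed with the library left out. Each such fit also holds fewer tumors and so has less power, so a lost call need not reflect that library alone. The counts higher and lower were 1216 and 1023 without vehicle 1, 411 and 112 without vehicle 2, 932 and 435 without vehicle 3, 591 and 155 without TP-18 1, 508 and 215 without TP-18 2, and 388 and 111 without TP-18 3. A core of 315 higher and 73 lower genes, 22.1% of the calls, passed in all 6 of these fits.

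**Figure D2:**
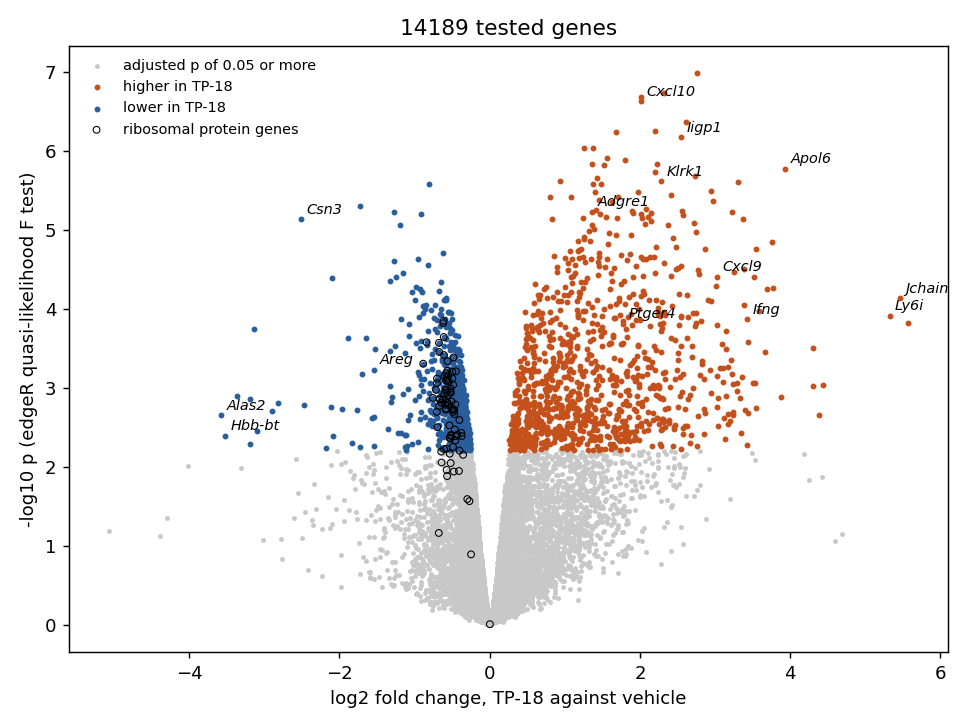
Log2 fold change of TP-18 against vehicle (horizontal) and -log10 of the unadjusted p (vertical) of the 14189 tested genes, with the 1006 higher calls in orange, the 747 lower calls in blue and ribosomal protein genes circled. The circled genes lie on the left in a narrow band, with a median log2 change of -0.56.

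Of the 32 gene lists, camera with a preset correlation called 16 higher and 5 lower in TP-18 tumors. With an estimated correlation none passed, although 9 lists had an unadjusted p under 0.05 by camera and the smallest adjusted p was 0.0601. By fry, which tests whether a list's genes move one way and not whether they differ from other genes, 13 lists were higher and 1 lower. Other splits of the 6 tumors into groups of 3 gave 17 to 24 camera calls with the preset correlation. The 2 largest shifts toward other tissues, which accompany each immune group described here, were skeletal muscle markers, with list scores higher by 1.86 (log2) in TP-18 tumors, and red blood cell markers, whose score fell by 3.04. Both separated the 3 vehicle from the 3 TP-18 tumors.

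Interferon gamma response genes rose as a group. Of 22 tested, 21 passed the test, and all 22 did when adjusted over the list alone. Their median log2 change was 2.01, with a camera adjusted p of 1.04e-67 (adjusted p = 0.0601 with an estimated correlation), and 18 members passed whichever library was left out. Iigp1, an interferon-inducible GTPase, rose from 60.9 ± 9.84 to 356 ± 64.7 CPM (log2 change 2.55 ± 0.17, adjusted p = 0.00118). Gbp7, a guanylate-binding protein of cell-autonomous defence, rose by 2.20 ± 0.15 (SE), and Psmb8, a catalytic subunit of the immunoproteasome, by 1.36 ± 0.11. Cd274, which encodes the checkpoint ligand PD-L1, measured 35.8 ± 15.8 and 94.7 ± 52.3 CPM, and its adjusted p of 0.136 missed the threshold. Type I interferon response genes, many of which respond to both interferon types, had 9 of 18 members higher, 11 when adjusted over the list alone. Their median was 0.95 (camera adjusted p = 9.86e-11, adjusted p = 0.295 with an estimated correlation), and 2 of the 9 passed whichever library was left out. Ifih1, a sensor of double-stranded RNA, rose by 1.06 ± 0.12, and Ifi44 by 1.49 ± 0.22. Stat2, which transmits interferon signals, rose by 1.37 ± 0.23 but had an adjusted p of 0.0720 without vehicle 2. Zbp1, a nucleic acid sensor, rose by 1.81 ± 0.28 and had an adjusted p of 0.0512 without vehicle 2 and 0.0552 without TP-18 1.

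T cell markers passed throughout, with 16 of 16 tested genes higher, the same number when adjusted over the list alone. The median log2 change was 2.22 (camera adjusted p = 6.91e-23, adjusted p = 0.0710 with an estimated correlation), and 9 of the 16 passed whichever library was left out. Cd6, a T cell surface receptor, rose from 0.403 ± 0.146 to 4.25 ± 1.54 CPM, Lck, the kinase that starts T cell receptor signalling, from 5.90 ± 1.31 to 19.0 ± 0.94 CPM, and Zap70, which acts after it, from 2.01 ± 0.26 to 7.32 ± 0.84 CPM. Cd247, the zeta chain of the receptor, rose by 2.48 ± 0.27. Cd4, the helper coreceptor, rose from 1.10 ± 0.64 to 4.39 ± 1.72 CPM (adjusted p = 0.0418). The call on Cd4 was lost without vehicle 2 (0.131), TP-18 1 (0.0618), TP-18 2 (0.0909) or TP-18 3 (0.140).

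CD8 and cytotoxic effector genes had 13 of 18 members higher, 17 when adjusted over the list alone, and all 18 changes were positive. The median was 1.99 (camera adjusted p = 1.59e-24, adjusted p = 0.0601 with an estimated correlation), and 10 of the 13 passed whichever library was left out. Klrk1, an activating receptor of cytotoxic lymphocytes, rose from 4.06 ± 0.94 to 19.7 ± 1.79 CPM, Nkg7, a cytotoxic granule protein, from 5.61 ± 0.999 to 20.8 ± 3.25 CPM, and Il2rb, a receptor chain for interleukins IL-2 and IL-15, from 30.8 ± 2.24 to 89.8 ± 17.4 CPM. Xcl1, a chemokine for cross-presenting dendritic cells, rose by 3.37 ± 0.33. Cd8a (Entrez 12525, chromosome 6, 71373427 to 71379171), the cytotoxic T cell coreceptor, measured 3.99 ± 3.10 CPM in vehicle and 22 ± 0.61 in TP-18 tumors, with a log2 change of 2.46 ± 0.52 and an adjusted p of 0.0347. That p fell to 0.000363 without vehicle 1, the vehicle tumor with the most Cd8a, and was 0.0914 without vehicle 2, 0.0574 without vehicle 3, 0.0953 without TP-18 1, 0.0899 without TP-18 2 and 0.101 without TP-18 3. The killing proteins granzyme B and perforin missed the threshold: Gzmb measured 40.2 ± 19.0 and 116 ± 43.3 CPM (log2 change 1.52 ± 0.47, adjusted p = 0.0984) and Prf1 39.3 ± 16.4 and 119 ± 37.2 CPM (1.6 ± 0.41, adjusted p = 0.0603), both above all vehicle values in all 3 TP-18 tumors. DESeq2 and limma-voom called both genes, Gzmb at adjusted p-values of 0.020 and 0.046 and Prf1 at 0.0031 and 0.028.

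NK cell markers had 7 of 8 members higher, also 7 when adjusted over the list alone, with a median of 2.10 (camera adjusted p = 8.50e-12, adjusted p = 0.0601 with an estimated correlation), and 4 of the 7 passed whichever library was left out. Ncr1, the NK receptor NKp46, rose from 2.32 ± 0.16 to 8.69 ± 0.84 CPM (log2 change 1.91 ± 0.18, adjusted p = 0.00182). Klrc1, Klrd1 and Klrb1c, further receptors of NK cells, rose by 2.15 ± 0.21, 2.04 ± 0.23 and 2.48 ± 0.30. T cell checkpoint and exhaustion genes had 9 of 13 members higher, 10 when adjusted over the list alone, with a median of 1.46 (camera adjusted p = 1.55e-11, adjusted p = 0.0601 with an estimated correlation), and 5 of the 9 passed whichever library was left out. Lag3 rose by 2.08 ± 0.20, Btla by 2.74 ± 0.28, Havcr2, the gene of TIM-3, by 1.46 ± 0.16, and the costimulator Icos by 1.90 ± 0.25. Regulatory T cell genes had 5 of 11 members higher, 7 when adjusted over the list alone, with a median of 1.73 (camera adjusted p = 3.92e-05, adjusted p = 0.141 with an estimated correlation), and 1 of the 5 passed whichever library was left out. Ikzf2, a transcription factor of regulatory T cells, rose by 2.32 ± 0.33. Foxp3, their defining factor, went from 0.487 ± 0.238 to 1.82 ± 0.51 CPM (adjusted p = 0.0376), and its adjusted p was 0.0513 without vehicle 1, 0.0849 without vehicle 2, 0.0565 without vehicle 3, 0.0581 without TP-18 1, 0.102 without TP-18 2 and 0.130 without TP-18 3. Il2ra, the high-affinity chain of the IL-2 receptor, rose by 2.17 ± 0.37 with 0.0589 without vehicle 2, and Tnfrsf18, a costimulator, by 1.62 ± 0.26 with 0.0506 without TP-18 3.

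Genes of antigen presentation were higher on both the class I and the class II side. For MHC class I, 7 of 14 members rose, 10 when adjusted over the list alone, with a median of 0.65 (camera adjusted p = 1.86e-10, adjusted p = 0.187 with an estimated correlation), and 6 of the 7 passed whichever library was left out. Tapbp, which loads peptides onto class I, rose from 215 ± 22.6 to 510 ± 79.9 CPM, and the peptide transporter subunit Tap2 from 84.8 ± 3.04 to 174 ± 28.5 CPM. Tapbpl rose by 1.26 ± 0.09 and Erap1, which trims peptides, by 0.93 ± 0.08. For MHC class II, 9 of 12 members rose, 12 when adjusted over the list alone, with a median of 2.40 (camera adjusted p = 6.79e-13, adjusted p = 0.187 with an estimated correlation), but 0 of the 9 passed in every fit with a library left out. Ciita, the master regulator of class II, rose from 2.74 ± 2.04 to 28.3 ± 2.18 CPM (adjusted p = 0.0173), with 0.0546, 0.0569 and 0.0632 without TP-18 1, 2 and 3 in turn. H2-Ob rose by 2.69 ± 0.44 (0.0573 without vehicle 2), from 12 reads in vehicle to 89 in TP-18 tumors. H2-DMa, which edits peptides on class II, rose by 1.59 ± 0.30, with 0.0860 without vehicle 2, 0.0714 without TP-18 1, 0.0747 without TP-18 2 and 0.0807 without TP-18 3. Ifi30, a thiol reductase of antigen processing, rose by 0.96 ± 0.20, with 0.0965 without vehicle 2, 0.0742 without TP-18 2 and 0.0897 without TP-18 3. The reference is from C57BL/6J mice, whose MHC and NK receptor loci differ from those of BALB/c, so absolute levels of these genes depend on how reads mapped.

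Dendritic cell genes had 8 of 15 members higher, 9 when adjusted over the list alone, with a median of 1.41 (camera adjusted p = 5.01e-08, adjusted p = 0.0601 with an estimated correlation), and 4 of the 8 passed whichever library was left out. Wdfy4, required for cross-presentation, rose from 10.2 ± 2.99 to 32.1 ± 1.58 CPM. Il12b, a subunit of interleukin-12, rose by 3.01 ± 0.39, Xcr1, the receptor for Xcl1, by 3.44 ± 0.55, and Batf3, a factor of cross-presenting dendritic cells, by 2.70 ± 0.47, on 20, 42 and 16 reads in vehicle against 186, 514 and 119 in TP-18 tumors. Macrophage and monocyte markers had 5 of 17 members higher, 10 when adjusted over the list alone, with a median of 0.77 (camera adjusted p = 1.66e-08, adjusted p = 0.195 with an estimated correlation), and 3 of the 5 passed whichever library was left out. Adgre1, which encodes F4/80, rose from 32.8 ± 5.39 to 84.5 ± 6.39 CPM and Mpeg1, a pore-forming protein of phagocytes, from 131 ± 25.4 to 454 ± 120 CPM. Ms4a7 rose by 1.34 ± 0.20. Fcgr1, a high-affinity Fc receptor, rose by 1.18 ± 0.24, with 0.0645 without vehicle 1, 0.0691 without TP-18 1, 0.0679 without TP-18 2 and 0.0704 without TP-18 3. B cell and plasma cell markers were scarce. Of 5 tested, 4 rose, also 4 when adjusted over the list alone, with a median of 2.82 (camera adjusted p = 8.65e-06, adjusted p = 0.104 with an estimated correlation), and of the 4 only Jchain passed whichever library was left out. Jchain, the joining chain of secreted antibodies, had 2, 2 and 0 reads in the vehicle and 35, 96 and 85 in the TP-18 tumors. Mzb1, a plasma cell chaperone, had 1, 3 and 0 against 13, 34 and 25 reads, with an adjusted p of 0.0700 without TP-18 2 and 0.0768 without TP-18 3. Lymphoid chemokine and tertiary lymphoid structure genes had 3 of 10 members higher, 4 when adjusted over the list alone, with a median of 1.12 (camera adjusted p = 0.000333, adjusted p = 0.187 with an estimated correlation), and 2 of the 3 passed whichever library was left out. Ltb, lymphotoxin beta, rose by 2.13 ± 0.24 and Cd40, a costimulator of antigen-presenting cells, by 2.08 ± 0.24. Tnfsf13b, the B cell survival factor BAFF, rose by 1.59 ± 0.29, with 0.0591 without vehicle 2, 0.0564 without TP-18 1 and 0.0605 without TP-18 3, and Ccr7, a homing receptor, had a log2 change of 1.24 (adjusted p = 0.0511).

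The suppressive, inflammatory and neutrophil lists were not called with all 6 libraries. Of the 18 immunosuppressive and alternative-activation genes, 2 rose and 1 fell, the same numbers when adjusted over the list alone, and the list had a median of -0.09, a mean of 0.08 and a camera direction of up (adjusted p = 0.983). Arg1, arginase, measured 181 ± 103 and 175 ± 59.6 CPM (adjusted p = 0.962), and Nos2, inducible nitric oxide synthase, 23 ± 24.7 and 48.1 ± 44.1 CPM (adjusted p = 0.542). The members that passed were Trem2, a lipid receptor of macrophages, which rose by 0.76 ± 0.17, Spp1, osteopontin, with a log2 change of -0.54 ± 0.14, and Ido1, a tryptophan-degrading enzyme induced by interferon gamma, which rose by 3.42 ± 0.83 and was chosen after its values were seen. Ido1 had an adjusted p of 0.0459, which rose above the threshold without any one library: 0.101 without vehicle 1, 0.0616 without vehicle 2, 0.0530 without vehicle 3, 0.102 without TP-18 1, 0.0980 without TP-18 2 and 0.0852 without TP-18 3. Trem2 had adjusted p-values of 0.105 without vehicle 2, 0.0530 without vehicle 3 and 0.0523 without TP-18 3. Spp1 passed only without vehicle 3 (0.0489) and lost its call without vehicle 1 (0.0627), vehicle 2 (0.139), TP-18 1 (0.138), TP-18 2 (0.126) or TP-18 3 (0.0555). Inflammatory cytokines and myeloid chemoattractants had 1 of 20 members higher, also 1 when adjusted over the list alone, with a median of -0.39 (camera adjusted p = 0.934). That member was Tnf, the macrophage and T cell cytokine, which rose by 1.85 ± 0.25, while Lif had a log2 change of -0.78 (adjusted p = 0.0855). Of 13 neutrophil markers none passed by edgeR, nor when adjusted over the list alone, and the median was -0.56 (camera adjusted p = 0.832). S100a8 and S100a9, subunits of calprotectin, measured 27.9 ± 35.2 and 80.4 ± 101 CPM in vehicle and 12.8 ± 3.07 and 33.3 ± 5.52 CPM in TP-18 tumors (adjusted p = 0.520 and 0.453). Retnlg and Trem1 had log2 changes of -1.37 and -0.70. Vehicle 3 had the highest scores for both lists, 1.39 above the mean of all tumors for neutrophil markers and 1.19 for inflammatory cytokines, and without it both lists were called higher in TP-18 tumors, at adjusted p-values of 0.0484 and 0.000101. None of the 7 mast cell and eosinophil markers passed by edgeR, 2 did when adjusted over the list alone, and the list had a median of 1.82 (camera adjusted p = 0.00159, adjusted p = 0.369 with an estimated correlation). Cpa3, Fcer1a, Ms4a2 and Kit, all mast cell genes, had log2 changes of 2.00, 1.89, 1.82 and 0.63 with adjusted p-values of 0.104, 0.0712, 0.0696 and 0.13.

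Among the drug's targets, Ptger4 (Entrez 19219, chromosome 15, 5233399 to 5244187), the EP4 receptor, rose from 2.23 ± 0.44 to 7.64 ± 2.02 CPM (log2 change 1.77 ± 0.27, adjusted p = 0.00770) and passed whichever library was left out. Ptger2, the EP2 receptor, measured 0.646 ± 0.377 and 1.99 ± 1.02 CPM and missed the threshold (1.62 ± 0.58, adjusted p = 0.105). Ptgs2, the inducible cyclooxygenase that makes the prostaglandin precursor, measured 485 ± 157 and 223 ± 65.5 CPM (-1.12 ± 0.31, adjusted p = 0.0669), and Pla2g4a, which frees its substrate arachidonic acid, had a log2 change of -0.43 (adjusted p = 0.0603). DESeq2 called Ptgs2 and Ptger2, at adjusted p-values of 0.016 and 0.040. Of 13 tested genes of prostaglandin synthesis, transport and reception, 1 rose, and when adjusted over the list alone 1 rose and 2 fell, with a median of 0.08 (camera adjusted p = 0.983). EP2 and EP4 raise cAMP, and of 18 cAMP and CREB response genes 3 fell, also 3 when adjusted over the list alone, with a median of -0.38 (camera adjusted p = 0.0108, adjusted p = 0.369 with an estimated correlation). The list's adjusted p was 0.0694 without vehicle 3. Junb, an AP-1 transcription factor, fell from 278 ± 28.0 to 167 ± 14.5 CPM (-0.73 ± 0.10, adjusted p = 0.00614). Areg, the EGF receptor ligand amphiregulin, fell from 16.1 ± 3.10 to 5.56 ± 2.05 CPM (-1.54 ± 0.27, adjusted p = 0.0158, and 0.0577 without TP-18 2). Egr1, an early growth response factor, fell from 532 ± 147 to 250 ± 32.0 CPM (-1.09 ± 0.20, adjusted p = 0.0203), with 0.0666, 0.0625 and 0.0610 without TP-18 1, 2 and 3 in turn. Nr4a1, a classical CREB target, had a log2 change of -0.73 (adjusted p = 0.0809).

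Proliferation genes had 1 of 20 members higher and none when adjusted over the list alone, with a median of 0.04 (camera adjusted p = 0.832). The single call was Top2a, a topoisomerase of dividing cells, which rose by 0.39 ± 0.10 (adjusted p = 0.0381) and was lost without vehicle 2 (0.131), vehicle 3 (0.0638), TP-18 1 (0.126) or TP-18 3 (0.123), and Mcm5, a replication helicase subunit, had a log2 change of 0.21. Hypoxia and glycolysis genes were called lower with 1 of 19 members passing and none when adjusted over the list alone, 17 of 19 changes being negative with a median of -0.55 (camera adjusted p = 0.00361, adjusted p = 0.701 with an estimated correlation). Without vehicle 3 the list's adjusted p was 0.182. Adm, adrenomedullin, had a log2 change of -1.18 ± 0.29 (adjusted p = 0.0382), and passed only without vehicle 1, with 0.12 without vehicle 2, 0.0824 without vehicle 3, 0.112 without TP-18 1, 0.0625 without TP-18 2 and 0.122 without TP-18 3. The glycolytic enzyme Eno1 had -0.55 (adjusted p = 0.0854). Of 14 p53 target and apoptosis genes 5 fell, 7 when adjusted over the list alone, with a median of -0.29 (camera adjusted p = 0.00971, adjusted p = 0.373 with an estimated correlation, and 0.0546 by camera without TP-18 1). Eda2r, a member of the TNF receptor family, had a log2 change of -0.70 ± 0.11 and passed in every fit. The death receptor Tnfrsf10b (-0.53), Phlda3 (-0.30) and the pore former Bax (-0.28) lost their calls without vehicle 2, vehicle 3, TP-18 1 or TP-18 3 (0.0598 to 0.104, 0.0563 to 0.114 and 0.0953 to 0.146 in that order of genes), and Phlda3 and Bax also without TP-18 2 (0.0951 and 0.10). The fifth, Bbc3 (-0.53, adjusted p = 0.0498), was named after its value was seen and passed only without vehicle 3 (0.0253), with 0.0909 without vehicle 1, 0.165 without vehicle 2, 0.143 without TP-18 1, 0.136 without TP-18 2 and 0.0851 without TP-18 3.

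Epithelial-mesenchymal transition genes had 2 of 11 members lower, and 5 lower and 1 higher when adjusted over the list alone, with a median of -0.22 (camera adjusted p = 0.0109, adjusted p = 0.167 with an estimated correlation). The list mixes epithelial genes such as Cdh1 with mesenchymal genes such as Fn1, which a transition would move in opposite directions. Its median and camera direction therefore do not measure a transition. Fn1, fibronectin, fell from 6569 ± 1127 to 4116 ± 294 CPM (adjusted p = 0.0248), with 0.0837 without vehicle 2, 0.0799 without TP-18 1, 0.0566 without TP-18 2 and 0.103 without TP-18 3. Twist1, a mesenchymal transcription factor, had a log2 change of -0.35 ± 0.08 (adjusted p = 0.0293) and passed only without vehicle 1, with 0.0655 without vehicle 2, 0.0638 without vehicle 3, 0.105 without TP-18 1, 0.0517 without TP-18 2 and 0.118 without TP-18 3. E-cadherin, Cdh1, measured 1.85 ± 0.71 and 4.09 ± 0.80 CPM (log2 change 1.15, adjusted p = 0.0647). Of 8 Wnt and beta-catenin targets 1 rose and 1 fell, 2 and 1 when adjusted over the list alone, with a median of 0.003 (camera adjusted p = 0.836). Myc fell from 226 ± 38.4 to 141 ± 10.0 CPM (-0.68 ± 0.13, adjusted p = 0.0163), with 0.0671 without vehicle 2, 0.0575 without TP-18 1 and 0.0577 without TP-18 2. Axin2, a feedback inhibitor of Wnt signalling, rose by 2.30 ± 0.53 (adjusted p = 0.0308) from 13 reads in the vehicle tumors to 74 in the TP-18 tumors, with 0.0542 without vehicle 1, 0.105 without vehicle 2, 0.0973 without TP-18 1, 0.0563 without TP-18 2 and 0.106 without TP-18 3.

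Stromal lists were not called. None of 16 endothelial markers passed by edgeR, nor when adjusted over the list alone (median 0.44, camera adjusted p = 0.233), and Eng and Tek, receptors of vessel walls, had log2 changes of 0.82 and 1.09. Without TP-18 1 the list was called higher (adjusted p = 0.0150). None of 18 fibroblast and matrix genes passed by edgeR, nor when adjusted over the list alone (median 0.10, camera adjusted p = 0.836), with decorin, Dcn, at -0.60 (adjusted p = 0.0507) and the smooth muscle actin Acta2 at 0.98, and the list was called higher without vehicle 3 (adjusted p = 0.0416).

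Markers of skeletal muscle and red blood cells differed between groups. Skeletal muscle markers had 9 of 16 members higher, 13 when adjusted over the list alone, with a median of 1.94 (camera adjusted p = 1.12e-09, adjusted p = 0.187 with an estimated correlation), and 3 of the 9, named first here, passed whichever library was left out. Atp2a1, the calcium pump of fast muscle, rose from 1.56 ± 0.63 to 9.17 ± 1.29 CPM, Myh4, a fast myosin, from 2.75 ± 0.39 to 11.4 ± 3.23 CPM, and Ckm, muscle creatine kinase, from 2.63 ± 0.79 to 10.5 ± 2.67 CPM. Tnnc2, fast troponin C, rose by 2.02 ± 0.38, with 0.0729 without vehicle 2, 0.0505 without TP-18 1 and 0.0732 without TP-18 3. Red blood cell markers fell, with 4 of 5 members passing, 5 when adjusted over the list alone, and a median of -3.31 (camera adjusted p = 1.18e-05, adjusted p = 0.222 with an estimated correlation). Alas2, the first enzyme of heme synthesis in red cell precursors, fell from 6.71 ± 5.22 to 0.560 ± 0.208 CPM, and the globins Hba-a1, Hba-a2 and Hbb-bt had log2 changes of -3.10, -3.19 and -3.52. Each of these 4 calls was lost without vehicle 2 (0.0848 to 0.107), TP-18 1 (0.106 to 0.137), TP-18 2 (0.0799 to 0.117) or TP-18 3 (0.115 to 0.157). Scores for red blood cell markers were 0.17, 1.68 and 2.71 above the mean of all tumors in vehicle 1, 2 and 3. Adipocyte markers had 1 of 7 members higher, 3 when adjusted over the list alone, with a median of 1.05 (camera adjusted p = 0.0144, adjusted p = 0.369 with an estimated correlation). Plin4, a lipid droplet coat protein, rose by 0.89 ± 0.18 (0.0633 without TP-18 1, 0.0864 without TP-18 3), and Lipe, Fabp4 and Car3 had log2 changes of 1.05, 0.98 and 2.42 that did not pass. TP-18 3 had the highest fat score, 1.22 above the mean, and without it the list's adjusted p was 0.0612. Skin and keratinocyte markers had 1 of 7 members lower, also 1 when adjusted over the list alone, yet a median of 2.29 (camera adjusted p = 0.832). Lgals7 had a log2 change of -0.67 ± 0.15, lost without vehicle 1 (0.0635), vehicle 3 (0.0501), TP-18 1 (0.0858), TP-18 2 (0.0816) or TP-18 3 (0.0570), and Trp63, the basal keratinocyte factor, had 2.41 (adjusted p = 0.128). Skin scores were 1.12, -1.40 and 2.31 relative to the mean in TP-18 1, 2 and 3, and without TP-18 2 the list was called higher (adjusted p = 0.000159).

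Lists tied to RNA quality were not called. None of 13 mitochondrially encoded genes passed by edgeR, nor when adjusted over the list alone (median -0.004, camera adjusted p = 0.832), with COX2 and ND6 at -0.27 and 0.51. Of 10 nuclear retained and histone transcripts 1 rose, also 1 when adjusted over the list alone (median -0.22, camera adjusted p = 0.832). That was Xist, which silences the second X chromosome of female cells, at 63.7 ± 22.9 and 155 ± 11.5 CPM (adjusted p = 0.0285), with 0.101 without vehicle 2, 0.0762 without TP-18 1, 0.0816 without TP-18 2 and 0.0901 without TP-18 3, and the histone gene H2bc4 had -0.77. The mitochondrial share of counts was 2.98%, 2.07% and 1.88% in the vehicle and 2.22%, 2.33% and 2.34% in the TP-18 tumors. Ribosomal protein genes took 9.36%, 10.8% and 10.9% against 8.33%, 7.64% and 7.76%.

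**Figure D3:**
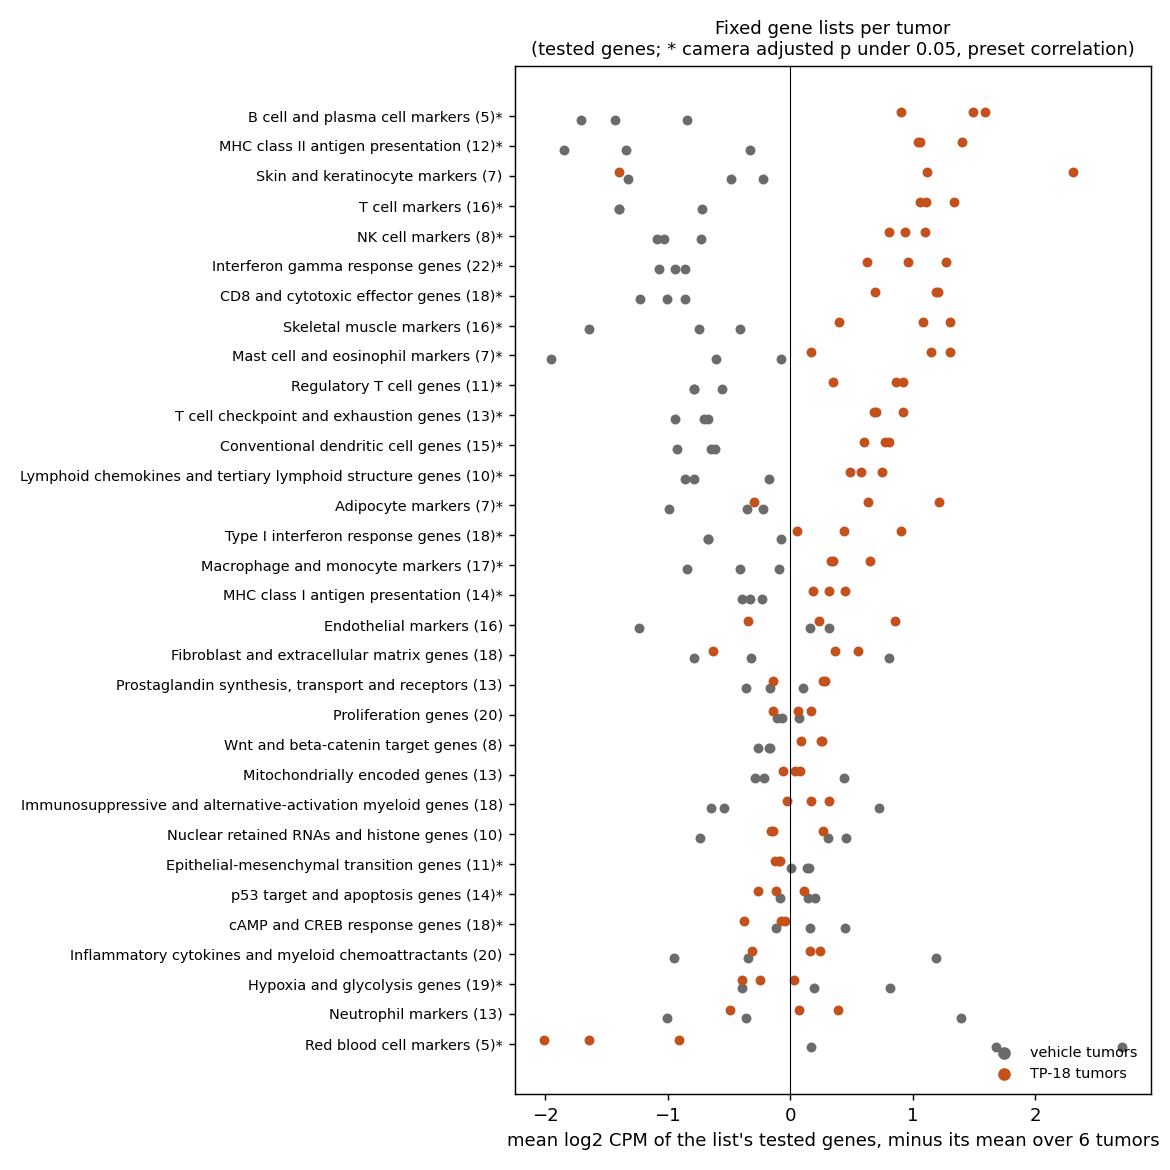
Mean log2 CPM of each list's tested genes in each tumor, minus the list's mean over the 6 tumors (horizontal), with vehicle tumors in grey, TP-18 tumors in orange and the number of tested genes in brackets. Stars mark a camera adjusted p under 0.05 with the preset correlation, and 18 lists separate the groups without overlap.

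Among the largest increases of protein-coding genes, Apol6, a member of the apolipoprotein L family, rose from 2.13 ± 0.07 to 32.7 ± 12 CPM (log2 change 3.94 ± 0.29, adjusted p = 0.00148). Ubd, the ubiquitin-like protein FAT10, rose by 3.69 ± 0.41, and Gm12185 by 3.76 ± 0.40. Calhm6, a channel protein of immune cells, rose by 3.59 ± 0.49, and Slc17a6, a vesicular glutamate transporter, by 3.75 ± 0.40. Mybpc1, a myosin-binding protein of slow muscle, rose by 3.67 ± 0.62 (adjusted p = 0.0508 without TP-18 3). With Jchain, given with the B cell genes, Ly6i, Gja5 and Fmod complete the 10 largest increases. Their group counts were 9, 11 and 9 reads in vehicle against 416, 278 and 225 in TP-18 tumors. Gja5 lost its call without vehicle 2 (0.0530), TP-18 2 (0.0516) or TP-18 3 (0.0648), and Fmod without vehicle 1 (0.0744), vehicle 2 (0.108), TP-18 2 (0.0566) or TP-18 3 (0.0709). Ly6i belongs to a family of close paralogs, as do the globins and Gbp genes, and how reads shared between paralogs were assigned is not given in the sources used here. The 10 largest decreases were the 4 red cell genes and 6 others. Csn3, kappa casein, fell from 13.5 ± 2.99 to 2.37 ± 0.54 CPM (-2.51 ± 0.25, adjusted p = 0.00182), Taf7l, a TAF-family transcription factor, had -3.13 ± 0.48, the serine protease Prss12 -2.09 ± 0.26 and Fam110c -1.89 ± 0.30. Vsig4, a complement receptor of resident macrophages, had -3.20 ± 0.67, with 0.0676 without vehicle 2, 0.0760 without TP-18 1, 0.0622 without TP-18 2 and 0.0869 without TP-18 3, and Sh2d6 had -1.96 ± 0.43, with 0.0891 without vehicle 2 and 0.0730 without TP-18 2.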

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

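Leaving out vehicle 3 and TP-18 3 together was chosen after the results were seen, and the other alternatives were planned. Each call kept its sign wherever it was tested, which was 1495 of the 1753 on filtered FPKM, 1659 with the 1 CPM filter and all under the others. The 1006 higher and 747 lower calls became 547 and 231 with the replicate number as a block and 395 and 86 with 2 tumors per group (without vehicle 3 and TP-18 3). Both fits leave less information on the spread between tumors and so have less power. How much of the change this accounts for was not tested. They became 1609 and 1413 at an adjusted p under 0.10, and 636 and 57 with at least a 2-fold change, where the threshold itself accounts for the change. Leaving out each library in turn gave 388 to 1216 higher and 111 to 1023 lower. DESeq2 called 1202 lower beside 1454 higher and shared 1742 calls. On log2 FPKM 235 genes were lower with a pseudocount of 1, 232 with 0.1 and 95 without a filter; the median of all genes was 0.10 and 0.11 in the filtered fits against -0.01 with TMM, the fits differ in scaling, filter, transform and test, and the cause was not tested. The share of higher calls went from 57.4% to 83.7% with a pseudocount of 1. RLE, upper-quartile scaling, the other filters, non-robust moderation and limma-voom stayed within 1.5 times both counts. With an estimated correlation 0 lists were higher and 0 lower, and with fry 1 was lower. Without each library 3 to 5 lists were lower. Neutrophil markers ranged from 0.0484 (without vehicle 3, then higher) to 0.784 and inflammatory cytokines and myeloid chemoattractants from 0.000101 (without vehicle 3, then higher) to 0.956, with 0.000442 (higher) in 2 tumors per group; vehicle 3 had the highest scores of both. Of 98 named genes past the threshold, 61 passed wherever they were tested in settings that kept every library without a block, and 98 kept their sign. Named genes were not scored at an adjusted p under 0.10 or with the 2-fold minimum. On filtered FPKM 71 kept and 7 lost their calls, with the 1 CPM filter 89 kept and 0 lost them, and the rest were not tested there. Genes under 1 CPM rest on few reads, which limits 30 of the 134 named genes, 26 of them past the threshold, that averaged under 1 CPM in at least 1 group, Ifng and Jchain among them.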

Other observations

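Pathway terms, the ribosomal and immediate early gene comparisons, and the tests of host tissue and of scaling were chosen after the results were seen. Ribosomal protein genes, the structural parts of the ribosome, were lower in TP-18 tumors. Of 84 tested, 69 fell and 0 rose by edgeR's quasi-likelihood test, 81 were lower when adjusted over the list alone, and the median log2 change was -0.56 (camera p = 2.88e-39, p = 0.0905 with an estimated correlation, both for a list chosen on these samples). Rpl24, of the large subunit, fell from 929 ± 83.4 to 605 ± 7.90 CPM (-0.62 ± 0.09 SE, n = 3 per group, adjusted p = 0.00770) and passed whichever library was left out. The KEGG term for the ribosome held 76 lower calls among 133 genes (hypergeometric adjusted p = 1.01e-54), against 6.53% of the background. That test treats genes as independent, while camera with an estimated correlation gave p = 0.0905 for the 84 ribosomal protein genes. Among higher calls, 54 of 314 KEGG terms passed, with natural killer cell cytotoxicity first at 39 of 108 genes (adjusted p = 1.61e-12) and T cell receptor signalling at 30 of 95, and these terms share many genes with the lists described in the report.

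Ligands of the EGF receptor fell with amphiregulin. The Reactome term for signalling by this receptor held 10 lower calls among 44 genes (adjusted p = 0.0113), against 6.04% of the background. Ereg, epiregulin, fell from 402 ± 41.9 to 178 ± 38.7 CPM (log2 change -1.18 ± 0.17, adjusted p = 0.00725) and Btc, betacellulin, from 102 ± 14.8 to 48.6 ± 9.19 CPM (-1.07 ± 0.16, adjusted p = 0.00932), and both passed whichever library was left out. Ereg and Btc were chosen after their values were seen. A Reactome term for the TGF-beta receptor complex also held an excess of lower calls, 12 of 66 (adjusted p = 0.0240).

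T cell markers were higher in all 3 TP-18 tumors than in any vehicle tumor. More host tissue of every kind would raise all host markers alike only if tumor cells expressed none of them, which was not measured. The T cell score rose by 2.10 more than the mean of the endothelial and neutrophil scores (2 SE = 0.82, and 1.88 to 2.43 without each library). That pair of lists was picked after the values were seen and had changes of only 0.50 and -0.02. The T cell score also rose by 1.39 more than the mean of 8 host lists (2 SE = 0.75). These gaps show that it rose more than those means, but cannot decide whether more host tissue was the whole cause. The T cell score exceeded 5 of the 8 lists by over 2 SE, those of endothelium, neutrophils, fibroblasts, macrophages and fat. It did not exceed 3 others by as much, since mast cell, skeletal muscle and skin scores were higher by 1.75, 1.86 and 1.35. More host tissue, and tissue that holds muscle, mast cells or skin together with T cells, therefore stay open. So do a larger T cell share under TP-18 and lymphoid tissue taken along, and the design has no further samples to separate them.

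Ribosomal protein transcripts are short and abundant, so a bias by length and level was tested with 126 other genes matched on both. These had a median log2 change of -0.24 (bootstrap 95% interval -0.287 to -0.174), above the ribosomal median of -0.56. The interval resampled genes and not tumors, so it holds no spread between tumors. The matched genes were less abundant (mean log2 CPM 8.38 against 9.58), yet with matches held within 0.5 log2 units of length and level 58 of 62 ribosomal genes lay below their matches, by a median of -0.29. Of TMM, RLE, upper-quartile and total-count scaling, the last brought the ribosomal median nearest to 0, at -0.41 with 54 genes lower and 0 higher (difference of library medians -0.40, 2 SE = 0.15). This argues against the choice among them as the whole cause, while the size of the decrease depends on it. Relative to the median of all genes, the ribosomal median was -0.549, -0.549, -0.547 and -0.543 in that order, since a scaling factor moves every gene alike. A lower share of ribosome-rich tumor cells in the TP-18 samples and an effect of treatment stay open, and part of the decrease may follow length and level, given the -0.24 of matched genes.

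Junb and Egr1, immediate early genes, can be induced within minutes of handling as well as by cAMP. A shorter time before freezing in the TP-18 group was therefore tested on 17 further immediate early genes. Their median log2 change was -0.45, with 15 of 17 negative, as a difference in handling time would give. By edgeR only 3 of the 17 passed, all lower, and Arc (1.03) and Btg2 (0.14) were positive without passing. Fosl1 (-0.58) passed whichever library was left out, Maff (-0.75) lost its call without vehicle 2 (0.0934), TP-18 1 (0.0788), TP-18 2 (0.0563) or TP-18 3 (0.0949), and Jun (-0.45) passed only without vehicle 1, at 0.0644 without vehicle 3, 0.11 without vehicle 2, 0.0812 without TP-18 1, 0.0880 without TP-18 2 and 0.0938 without TP-18 3. Lower receptor signalling under TP-18 would give the same values, and the labels give no times of collection, so neither is excluded. Other causes were not tested.

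The 6 tumors make 10 splits into groups of 3, too few for a share under 0.05. The real split called 1753 genes and the highest of the others 1, so that 1 of 10 splits, the real one, gave as many. For lists the real split called 21 and the highest of the others 24, so that 2 of 10 gave as many. Every other split called 17 to 24 lists while calling at most 1 gene, so the number of lists called with the preset correlation does not set the treatment split apart.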
